A study of Arabidopsis thaliana with 6 samples.

How the data were processed

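Gene expression was measured on 6 Agilent Arabidopsis oligonucleotide arrays with 2 colours, each with 21500 probes that are not controls. Per the labels, total RNA was extracted with Trizol from 28-day plants without roots, amplified linearly and labelled with Cy3 for the control and Cy5 for the SA-treated or SIB1-overexpressing plant, without a dye swap. Groups were taken from the labels: SA for 2, 5, 10 and 24 h with 1 array each, and overexpressor with 2 arrays of 2 differently named plants, called lines here.

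Per the file headers, the deposited array files hold Agilent Feature Extraction's spot columns, with the mean intensity of each spot and the median intensity of its local background in both channels, background-subtracted intensity, flags, and the software's dye-normalized log10 ratio of Cy5 over Cy3. The software version and settings, the slide and the scan day are not given in the sources used here. Per the file headers the arrays come in 2 column layouts, 1 shared by the 2 h SA array and both overexpressors and 1 by the other SA arrays. The deposited series table holds a further ratio per probe. Compared with the arrays it is a linear Cy5 over Cy3 ratio, since its log correlated with the computed log2 ratios at r = 0.946 to 0.993, with medians of 0.994, 0.959, 0.966 and 1.03 at 2, 5, 10 and 24 h and 1.00 and 1.01 in lines 1 and 2; how the authors normalized this ratio is not given in the sources used here. The deposited ratio is blank for 7067 probes at 2 h and for 4068 and 3940 in lines 1 and 2, so tests on it use fewer probes there.

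From the intensities, background was corrected with limma's normexp on mean and local background signals with an offset of 50, followed by loess within each array. Control spots and spots with outlier marks were left out, 10 to 25 spots on every array except the 24 h array, which had 1722 (8.01%). The analysis used R 4.3.3 and limma 3.58.1, with figures drawn in Python 3.11.15 and matplotlib 3.10.9. Of the probes, 21342 have 1 locus in the files and 158 have loci that differ between files and were left unnamed; 21157 loci were found in a RefSeq gene table of assembly TAIR10.1, used for names only. The files name no genome build, so no coordinates are printed.

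Tests used limma's lmFit and eBayes on log2 ratios against 0 with Benjamini-Hochberg adjustment, and a call needs an adjusted p under 0.05 and a mean change of at least 2-fold. A ratio against 0 leaves out the control's own spread. The overexpressor fit used its 2 arrays, the SA fit the 4 SA arrays and so the spread between times, the trend a slope on log2 of hours, and the difference all 6 arrays. Probes had to be well above background in at least 1 channel on both arrays of the overexpressor fit or on 2 arrays of the others, and to have values on both overexpressor arrays, on 3 of the 4 SA arrays, or for the difference on 4 arrays with both overexpressors; the requirement of values was added to the plan when the fits were written; this filter removes almost nothing on the 3 dim arrays, where the scanner software marks nearly every spot. Gene lists, groups, tests and alternatives were fixed before the data were examined, except those named in the closing section as chosen later. Lists were tested with camera at a preset correlation of 0.01, with camera's estimated correlation and with fry, and at single arrays against 10000 random lists matched on brightness. The 13 lists that pass with the preset correlation in the SA fit and the 2 in the overexpressor fit all miss the threshold with the estimated one. With fry 12 lists passed in the SA fit and 0 in the overexpressor fit.

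No named locus has more than 1 probe. Named genes were the 8 highest and 8 lowest calls with 1 sign on every array, filled where calls were too few by genes at least 2-fold on every array; the 3 highest and 3 lowest ratios at each SA time; the 4 highest and 4 lowest calls of the trend and the difference; up to 4 members of each list by size; up to 6 genes called in both sets; and SIB1, PR1, PR2, PR5, ICS1, WRKY70 and PDF1.2a. Probes saturated in both channels or without a gene (8 of the SA calls, 1 of the difference calls) were passed over. Genes named outside the rule, in counts of 5 or fewer, in the clock list and in some groups, were chosen after their values were seen. Where a channel was saturated, lacked the well-above-background mark or held the scanner software's surrogate value the ratio is a bound, computed per channel after quantile normalization of brightness and open to dye bias.

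The methods were tested on simulated data with 200 changed probes and variances drawn from the fitted prior. A first version drew from shrunken variances, overstated the recovery and was replaced. For the SA mean over 21280 probes, 32, 88, 96 and 98% of changes of log2 1, 2, 3 and 4 were recovered with 3 false calls; for the overexpressors over 21482 probes 0, 0, 42 and 70% with 2 false calls; for the difference 26, 70, 96 and 98% with 7. In a simulated set of 18 lists, the single moved list passed. Ratios of dim probes are compressed by the offset: the simulated slope of measured on true ratio for dim, middle and bright probes was 0.107, 0.251 and 0.567 on the 2 h array, and 0.439, 0.804 and 0.934 on the 24 h array. Alternatives changed the background correction, the normalization, the source of the ratios, the filter, the variance model, the thresholds, the arrays in the fit and saturated probes.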

Results

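The series holds 6 microarrays of RNA from 28-day Arabidopsis thaliana plants of the Columbia accession, sampled as the whole plant without its roots. Each array carried 21500 probes and compared a control RNA in the Cy3 channel with a treated or transgenic RNA in the Cy5 channel. In 4 arrays the Cy5 plants had received 5 mM salicylic acid (SA), the plant defence hormone, for 2, 5, 10 or 24 h, with 1 array per time, and the control plants were untreated. In the other 2 arrays the Cy5 plants overexpressed SIBA, the gene AT3G56710, named SIB1 in the reference table, and the controls carried the vector. SIB1 encodes a protein that binds a sigma factor of plastid RNA polymerase. The labels give the 2 overexpressor plants different names, and they are called line 1 and line 2 here. The labels do not say whether they came from separate transformations. The 2 h SA array and the overexpressor arrays were dim, with a median Cy5 signal above local background of 21.5, 79 and 84, against 206.5, 300 and 404 at 5, 10 and 24 h, and their files have another column layout. The number of arrays limits the precision of every value. The labels do not say that the RNAs came from separate cultures or that the control RNAs differed between arrays, so the p-values measure only the spread between these arrays, which may be in part technical. Dyes were never swapped, so a probe that favours 1 dye would shift its log2 ratio the same way on all 6 arrays, by an amount that depends on how far ratios are compressed there. Values are log2 ratios of the Cy5 plant over its own control.

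The comparison of overexpressors with the vector control asks which genes changed with SIB1. SIB1 itself stood far above the control in both lines, with log2 ratios of 5.25 in line 1 and 5.59 in line 2, a mean of 5.42 ± 0.243 (SD, n = 2) or 42.9-fold. The next highest mean over the lines was 2.72. With 2 arrays the moderated test of limma called no probe out of 21482, SIB1 included (adjusted p = 0.664), and 995 probes had an unadjusted p under 0.05 where chance alone gives 1074. SIB1 became the single call, with an adjusted p of 0.0127, when the variance was allowed to follow brightness, and it also passed under median centring of the arrays (adjusted p = 0.0421). In data simulated for this design, the test found 0% of changes of log2 2, 42% at log2 3 and 70% at log2 4, so changes of a few fold were not detectable. Under median centring in place of the loess curve, limma called 412 probes, 406 of them higher.

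Because the test made no call, genes at least 2-fold the same way in both lines are described by size alone. There were 23 such genes higher and 11 lower, where independent lines would share 0.769 and 0.407. That expectation would not hold if both arrays used the same vector control RNA or if the lines came from 1 transformation. The labels leave both open. It also treats all probes alike, while simulated slopes in lines 1 and 2 were 0.155 and 0.164 for dim and 0.776 and 0.773 for bright probes. Bright probes thus reach 2-fold more readily on both arrays, which raises the overlap. The 23 include SIB1, which the construct raises. After SIB1, the largest mean ratios belonged to the legume lectin gene AT3G16530 (mean 2.72), the glycine-rich protein gene GRP3S (1.84 and 3.53 in lines 1 and 2), the glutathione S-transferase gene GSTF2 (1.73 and 2.73), a further legume lectin gene, AT3G15356 (1.90 and 2.16), the histone deacetylase gene HDA18 (1.74 and 2.27), AT1G21050 (1.14 and 2.79) and WAVH2 (1.37 and 2.27). The lowest were AT1G19960 (-1.64 and -4.08), the lectin-like gene AT5G03350 (-2.17 and -3.27), the thionin gene THI2.2 (-1.23 and -3.49), CER1 of cuticular wax synthesis (-1.69 and -2.83), the ankyrin repeat gene ANK (-1.65 and -2.52), AT1G13650 (-1.05 and -2.94), LURP1, a defence gene induced by pathogens (-1.20 and -2.44), and ESP, which directs glucosinolate breakdown (-1.20 and -2.21). None of these passed the test (adjusted p = 0.664 for each), and dyes were not swapped. On the same dyes WAVH2 was below 0 at all 4 SA times, at -0.40 or less, while LURP1 and AT5G03350 were at 3.12 or more and 2.75 or more; a dye effect in the line ratios of these genes is not excluded by this. The counts were 133 higher and 5 lower under median centring, 46 and 22 with a smaller normexp offset of 16, 47 and 23 in the authors' ratio table, and 229 and 119 with the scanner software's own ratios. The scanner software put a surrogate value, its substitute for a signal near background, in the control of WAVH2 in line 1, where the ratio is a bound of at least 2.58-fold.

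**Figure D1:**
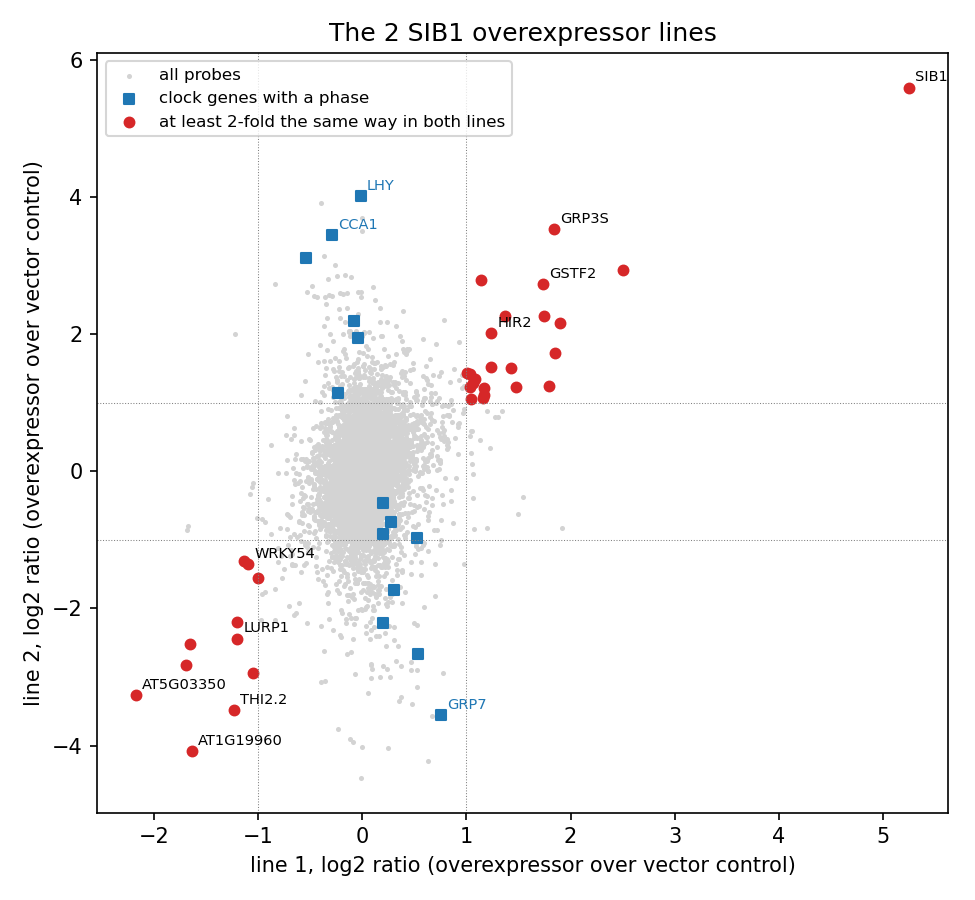
Log2 ratio of overexpressor over vector control in line 1 (horizontal) against line 2 (vertical), with 1 point per probe and dotted lines at 2-fold. Red points are the 34 genes at least 2-fold the same way in both lines, with SIB1 at 5.25 and 5.59, and blue squares are clock genes with a morning or evening phase. Of the whole clock list of 15, 11 reach 2-fold in line 2 and 0 in line 1, counting PRR7 (-1.49 in line 2), which is not drawn.

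Of the 13 measured defence genes that respond to SA, SIB1 was the only one at least 2-fold higher in both lines, and LURP1 and the aspartyl protease gene AED1 (-1.13 and -1.31) were at least 2-fold lower. The list tested lower than other genes with camera at a preset correlation (median -0.13, adjusted p = 0.0169; adjusted p = 2.94e-04 without SIB1), but had an adjusted p = 0.867 with an estimated correlation and 0.629 with fry. Over the list alone, 1 member passed higher (SIB1) and 1 lower. Other members were ACD6, an ankyrin protein of defence control (-1.68 and -0.80), the kinase gene WAK1 (-0.97 and -0.70), the marker PR5 (-0.56 and -1.37), PR1 (0.02 and -0.01) and PR2 (-0.11 and -0.15). WRKY54 (-1.10 and -1.36) and WRKY70 (-0.94 and -1.76), transcription factors of SA signalling, were also below the vector control, while the median of the 20 WRKY genes was -0.01 (adjusted p = 0.638). ICS1, the SA synthesis enzyme, had ratios of -0.05 and -0.10. PDF1.2a, a jasmonate marker, had 0.76 in line 1 and -0.72 in line 2.

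Among nuclear photosynthesis genes unsaturated on each array, the median was 0.00 over 18 genes in line 1 and -0.50 over 26 genes in line 2, where 22 were negative; this difference between lines was not tested. The 18 members never saturated in either line tested lower with camera (median -0.29, 16 negative, adjusted p = 0.0147), with an adjusted p = 0.867 with an estimated correlation and 0.732 with fry, and no single member was called. All 25 members with a value in both lines gave a median of -0.26 (adjusted p = 2.08e-04), but several are at the scanner's limit, and under median centring the list passed the other way (median 0.36, adjusted p = 0.0291). The genes for plastid sigma factors had a median of -0.04 (camera adjusted p = 0.817). SIG5, a light and stress responsive member, had -0.37 in line 1 and 2.12 in line 2, and SIG2 had 0.01 and -0.71.

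No other list passed in the overexpressors. Heat shock genes had a median of 0.27 (adjusted p = 0.548): HSP70-4, MBF1C and HSP101 had log2 ratios of 2.23, 2.61 and 1.48 in line 2 and -0.22, -0.05 and 0.03 in line 1. Abscisic acid and dehydration genes had a median of -0.19 (adjusted p = 0.345), with the cold-responsive COR15A at -0.36 in line 1 and -3.05 in line 2. Jasmonate and ethylene genes had -0.08 (adjusted p = 0.212), SA synthesis genes -0.07 (0.426), SA modification enzymes 0.07 (0.345), glutathione S-transferase and detoxification genes 0.03 (0.345), senescence genes 0.06 (0.566), pattern-triggered immunity genes 0.02 (0.638), auxin genes 0.06 (0.834) and endoplasmic reticulum chaperones -0.01 (0.834), each adjusted p from camera. The median and the mean differed in sign for the sigma factor, auxin, chaperone, clock and seed lists. Markers of flowers (-0.07, adjusted p = 0.110), seeds (-0.01, 0.834) and roots (0.05, 0.638), kept as a check of the organs sampled, did not pass. The circadian clock list did not pass either (-0.22, adjusted p = 0.834), but its members moved apart in line 2: LHY and CCA1, which peak in the morning, were at 4.01 and 3.44, and GRP7 and PRR5, which peak later, at -3.55 and -2.67. In line 1 no clock gene reached 2-fold, against 11 of 15 in line 2. In line 2, 403 probes were at least 2-fold higher and 486 lower, against 41 and 18 in line 1.

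**Figure D2:**
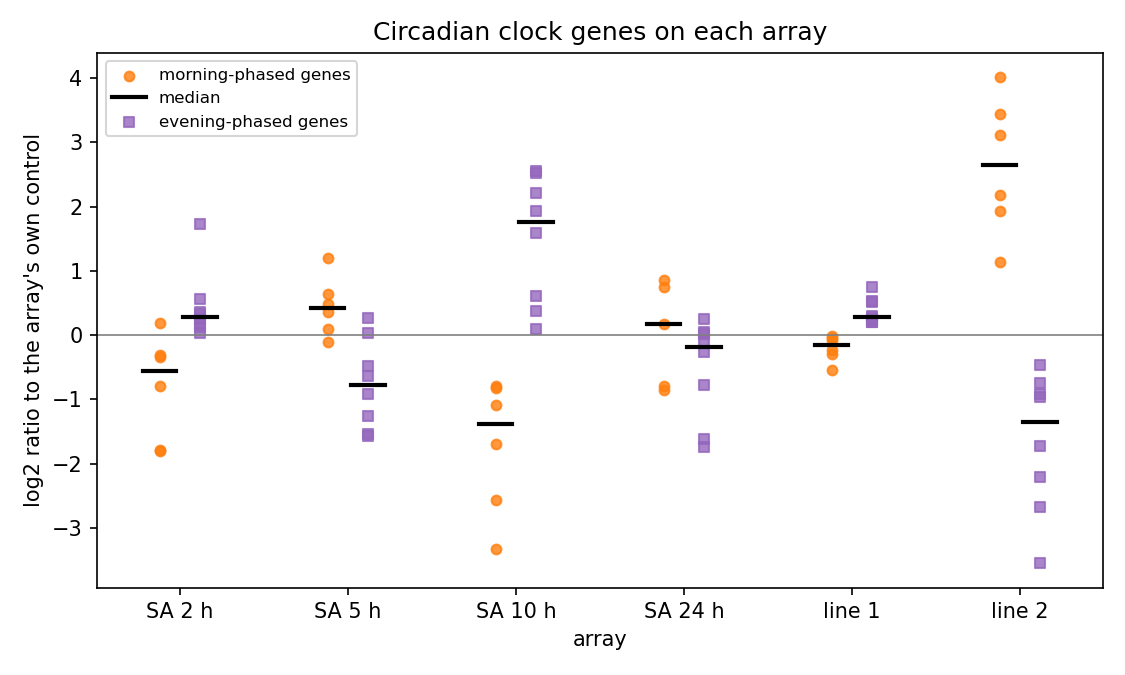
Log2 ratio to the array's own control of each clock gene with a morning or evening phase on the 6 arrays. Morning-phased genes are circles, evening-phased genes squares and medians black bars. In line 2 the morning median was 2.65 and the evening median -1.35, and at 10 h of SA they were -1.39 and 1.76.

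The SA arrays ask how SA changes expression over 24 h. Among called genes, the highest mean ratio was that of AT4G01870 (6.18 ± 1.25, SD over 4 times; adjusted p = 0.0151), whose treated channel was saturated at 5 h, where it was at least 144-fold higher. It was followed by the glucosyltransferase genes UGT76B1, AT3G11340 (4.87 ± 0.595, adjusted p = 0.0112), and UGT74E2, AT1G05680 (4.87 ± 1.33, adjusted p = 0.0213), the glutaredoxin genes GRX480, AT1G28480 (4.69 ± 0.693), and GRXS13, AT1G03850 (4.69 ± 0.810), UGT85A1 (4.66 ± 1.18), the NAC transcription factor gene ATAF2 (4.65 ± 1.40) and NIMIN1, AT1G02450, whose product binds the SA receptor NPR1 (4.64 ± 0.672). Each was above its control at all 4 times.

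The lowest mean among called genes was that of AT1G73600, a phosphoethanolamine methyltransferase gene (-2.24 ± 0.325, adjusted p = 0.0124). Next were AT1G29660, a GDSL lipase gene (-2.20 ± 0.586), the protein kinase gene CIPK20 (-1.99 ± 0.783), the fumarase gene FUM2 (-1.98 ± 0.571), IMD1 of leucine synthesis (-1.90 ± 0.789), the aspartate kinase gene AK3 (-1.88 ± 0.615), SCO1, a plastid translation factor (-1.85 ± 0.864), and CHLI2, a subunit of the chlorophyll synthesis enzyme magnesium chelatase (-1.85 ± 0.468).

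In all, limma called 799 of 21280 probes for a shift shared by the 4 times (adjusted p under 0.05 and at least 2-fold), 596 higher and 203 lower. The error is the spread between times, since no time had a replicate. The count depends on single arrays: without the 5 h array 0 probes passed (smallest adjusted p = 0.0521, 3763 at an unadjusted p under 0.05), without the 10 h array 0 (0.0546, 4673), without the 24 h array 154 and without the 2 h array 819. Every SA call named in the text is therefore lost without the 5 h or the 10 h array. All 799 probes kept their sign in each of these fits and 91.6 to 96.6% kept a 2-fold mean. They were chosen for a shared shift on the same 4 arrays, so this says little about stability. Median centring gave 1040 higher and 86 lower, and with the authors' own ratios 893 and 532; over all processing alternatives with the same threshold the count lay between 670 and 1425.

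SIB1 rose with SA as well, at 4.46, 3.71 and 2.88 after 2, 5 and 10 h (mean 3.68 ± 0.785, n = 3, adjusted p = 0.0242); its 24 h spot was marked as an outlier by the scanner software and left out. Among 18 measured genes of SA synthesis and signalling, 6 were called higher, 0 lower and 12 were not called (7 higher when adjusted over the list alone). They were NIMIN1, the lipase-like defence regulator PAD4 (2.15), the SA receptor gene NPR3 (1.87), the SA transporter gene EDS5 (1.66), the transcription factor gene CBP60g (1.58) and NPR1 (1.13 ± 0.20). ICS1 had 2.65 at 5 h and 0.49, -0.21 and -0.37 at 2, 10 and 24 h (adjusted p = 0.543). Camera takes only genes with a value on all 4 arrays, here and in the SA lists below: 15 of these 18, 11 of 13 defence outputs, 19 of 20 WRKY, 26 of 27 detoxification, 14 of 16 heat shock, 15 of 16 senescence, 21 of 23 auxin, 21 of 25 jasmonate, 14 of 15 clock and 9 of 10 flower genes. The list passed camera (median of the 15 genes 0.64, adjusted p = 2.68e-06) but not with an estimated correlation (adjusted p = 0.175). It also passed with fry (adjusted p = 0.012), as 12 lists did in the SA fit. Of 6 SA modification enzymes, UGT76B1, UGT74F2 (4.07) and DMR6, which hydroxylates SA (2.66), were called higher and 0 lower, with 4 higher when adjusted over the list alone; the list had an adjusted p = 6.77e-05 with camera and an adjusted p = 0.175 with an estimated correlation. BSMT1, the SA methyltransferase, stayed near 0 (0.06). As with all SA calls, none of these passed without the 5 h or the 10 h array.

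Of the 13 measured defence outputs, GRX480, SIB1 and LURP1 (3.47 ± 0.335) were called higher, 0 lower and 10 not called (5 higher when adjusted over the list alone). The classical marker PR1 was not among them: its log2 ratios were 0.10, 0.71, 2.47 and 2.89 at 2, 5, 10 and 24 h (adjusted p = 0.159), and at 2 h its control held a surrogate value. PR2 (mean 0.12, adjusted p = 0.472) and PR5 (0.33, adjusted p = 0.373) stayed below 2-fold at all 4 times. The list passed camera (median 0.58, adjusted p = 1.18e-04; adjusted p = 0.175 with an estimated correlation). All but 1 of the 20 WRKY transcription factors had a positive mean, and 11 were called higher and 0 lower (13 higher when adjusted over the list alone), among them WRKY40 (3.02), WRKY75 (2.77), WRKY38 (2.70) and WRKY70 (2.42 ± 1.09, adjusted p = 0.0437). This list had an adjusted p = 7.08e-10 with camera and an adjusted p = 0.0771 with an estimated correlation.

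Of 27 glutathione S-transferase and detoxification genes, 12 were called higher, 0 lower and 15 not called; adjusted over the list alone, 21 were higher and 1 lower. UGT74E2, GSTU24 (4.42), the cytochrome P450 gene CYP81D8 (3.96) and GSTU7 (2.95) were the highest called members. Of 16 heat shock genes, 12 were called higher, 0 lower and 15 higher when adjusted over the list alone, led by HSP70-4 (3.59), HSP101 (2.68), HSP17.6B (2.40, over 3 times) and the heat shock factor gene HSFB1 (2.16). Of 16 genes of senescence and darkness, 7 were called higher and 0 lower (11 higher when adjusted over the list alone), including SAG21 (4.64), the blue copper protein gene BCB (3.96), NAC102 (3.58) and the sugar-repressed gene DIN10 (9.88-fold). With camera these lists had adjusted p = 1.48e-11, 2.76e-09 and 3.44e-08, and adjusted p = 0.175, 0.175 and 0.0771 with an estimated correlation. Among 14 genes of pattern-triggered immunity and camalexin, MPK11 (1.70), BIK1 (1.65) and BAK1 (1.12) were called higher and 0 lower (7 higher when adjusted over the list alone; adjusted p = 4.19e-06 with camera, adjusted p = 0.175 with an estimated correlation), and the camalexin enzyme gene PAD3 had 3.02 (adjusted p = 0.0689).

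The median of endoplasmic reticulum chaperone and secretion genes was -0.36 at 2 h, 0.87 at 5 h, 1.81 at 10 h and 0.42 at 24 h, and 14 of 17 were at least 2-fold higher at 10 h, with BIP3 at 4.39 and PDIL1-2 at 3.12. No member was called over the 4 times, over all probes or adjusted over the list alone. The list passed camera (median 0.85, adjusted p = 9.45e-04) but had an adjusted p = 0.469 with an estimated correlation and 0.219 with fry.

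Of the 6 plastid sigma factors, SIG1 (-1.42 ± 0.57, adjusted p = 0.0369), SIG6 (-1.29) and SIG2 (-1.14) were called lower, 0 higher and 3 not called, with 3 lower adjusted over the list alone; all 6 had a negative mean. The list had an adjusted p = 1.53e-04 with camera and an adjusted p = 0.175 with an estimated correlation. Of 34 nuclear photosynthesis genes, PSAD2 of photosystem I was called lower (-1.15, adjusted p = 0.0455), 0 higher and 33 not called, and no member passed when adjusted over the list alone. The brightest of these genes are at the scanner's limit: 15 members at 24 h were saturated in both channels, where the ratio of -0.59 is set by the normalization. The 14 members never saturated on the SA arrays all had a negative mean, with a median of -0.46 (camera adjusted p = 7.58e-04, adjusted p = 0.424 with an estimated correlation and 0.141 with fry). Over the members unsaturated on each array, 28, 20, 16 and 16 at 2, 5, 10 and 24 h and so not the same genes, the medians were -0.04, -0.35, -0.87 and -0.39, at percentiles 52.68, 18.02, 0.31 and 9.52 of random lists matched on brightness. PSAH2 and LHCB4.2 had -1.55 and -2.19 at 10 h.

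Of 23 auxin response genes, the repressor gene IAA3 was called lower (-1.73, adjusted p = 0.0240) and 0 higher; adjusted over the list alone, 1 was higher and 2 lower. PIN7, an auxin transporter, had -1.21 (adjusted p = 0.0836), and GH3.3, which conjugates auxin, had 2.89 (adjusted p = 0.0551). The list passed camera downward (median -0.47, adjusted p = 0.00316; adjusted p = 0.175 with an estimated correlation). Of 25 jasmonate and ethylene genes, the jasmonate synthesis enzyme gene OPR3 was called higher (2.51, adjusted p = 0.0469), 0 lower and 24 not called, and none passed when adjusted over the list alone. This list passed camera (median of 21 genes 0.29, adjusted p = 0.00825; adjusted p = 0.175 with an estimated correlation) but not without the 2 h array (adjusted p = 0.0824). PDF1.2a had a mean of -0.06 over 3 times.

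Of 17 abscisic acid and dehydration genes, ABI1 (1.08) and HAI1 (1.03), protein phosphatases of the pathway, were called higher, 0 lower and 15 not called; 3 were higher and 1 lower when adjusted over the list alone, and the list did not pass (adjusted p = 0.635). The cold- and drought-responsive COR15A had 0.74 at 2 h and -4.19 at 24 h. Clock genes had 0 calls of 15 (adjusted p = 0.351), flower markers 0 of 10 (0.908; the median of the members tested was 0.01 and camera's direction was down), seed markers 0 of 4 (0.605) and root markers 1 of 3, PYK10, lower (-1.06, adjusted p = 0.0442; list adjusted p = 0.306). The medians of morning and evening clock genes differed by -0.85, 1.21, -3.15 and 0.35 at 2, 5, 10 and 24 h, at percentiles 0.04, 99.96, 0 and 86.27 of random pairs of lists matched on brightness, and 9 of 15 clock genes were at least 2-fold at 10 h. The labels do not say whether treated and control plants were sampled at the same time of day. A difference in sampling time is therefore not excluded at any SA time, the chaperone median at 10 h included, nor for the calls over the 4 times. At 24 h, 3 of 14 clock genes were at least 2-fold.

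**Figure D3:**
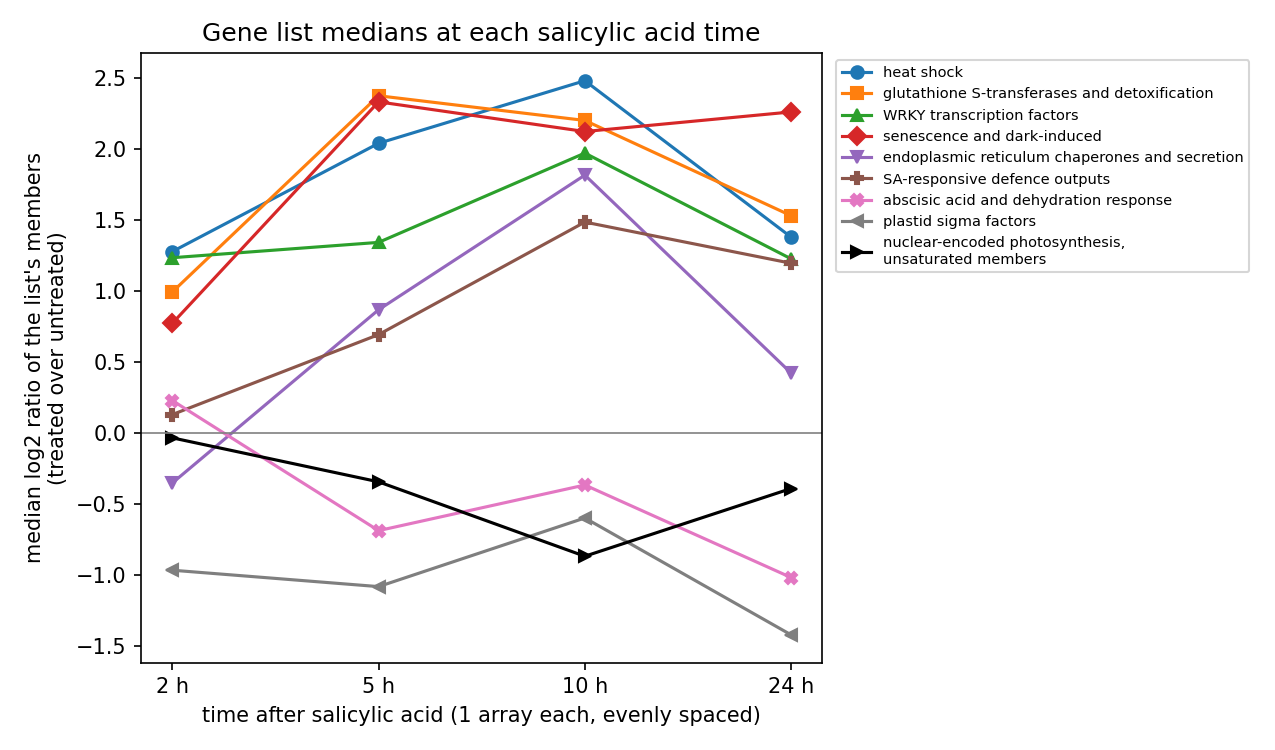
Median log2 ratio of SA-treated over untreated plants for 9 gene lists at 2, 5, 10 and 24 h, 1 array per time, with times evenly spaced. Heat shock and detoxification genes were at 0.99 or higher at all 4 times, chaperones of the endoplasmic reticulum peaked at 10 h with 1.81, and plastid sigma factors were at or below -0.60 throughout.

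Single times have no replicate and no p-value. At 2 h, 826 probes were at least 2-fold higher and 497 lower; at 5 h 1307 and 785; at 10 h 1568 and 951; at 24 h 1051 and 1113. Median centring gave 1516 and 164 at 2 h, 2198 and 723 at 10 h and 1580 and 887 at 24 h, and the authors' ratios 1080 and 1112 at 2 h. The order of the times is not settled, since ratios are compressed most at 2 h. There the simulated slope for middle probes was 0.251, against 0.707, 0.728 and 0.804 at 5, 10 and 24 h. With the scanner software's ratios 2 h had the most 2-fold probes, 4502 against 2941, 3708 and 3080. Across 19534 probes measured at all times, 337 were at least 2-fold higher and 49 lower at all 4, and 105 were so in opposite directions at different times. At 2 h the highest ratios were AT4G01870 (7.17), ATAF2 (6.19) and the zinc finger gene STZ (6.07), and the lowest emb2726 (-2.95), AT4G28080 (-2.66) and SHD (-2.64), a chaperone gene of the endoplasmic reticulum. At 5 h AT4G01870, UGT74E2 (5.83) and UGT85A1 (5.77) were highest, and COR15B (-3.90), AT4G30650 (-3.79) and the expansin gene EXPA8 (-3.55) lowest. At 10 h PCR1, a cadmium resistance gene (5.60), stood between AT4G01870 (5.79) and UGT74E2 (5.24), while the cell wall enzyme gene XTH31 (-4.08), LHCB2.3 (-3.97) and AT1G13650 (-3.59) were lowest. At 24 h PCR1 (4.98), AT1G30700 (4.75) and ELI3-2 (4.68) were highest, and COR15A (-4.19), MFP1 (-4.02) and COR15B (-3.95) lowest.

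The time trend asks which ratios rise or fall from 2 to 24 h. With 4 arrays limma called no probe (smallest adjusted p = 0.961), and 980 probes had an unadjusted p under 0.05 where chance gives 1064. In simulated data the same test recovered 20% of slopes of log2 1 per doubling of time and 90% of slopes of log2 2. A slope of log2 2 is steeper than that of ELI3-2, which rose from 0.10 at 2 h to 4.68 at 24 h. Its slope was 1.29 per doubling and was not called (limma adjusted p = 0.961). The absence of calls therefore says little about slopes of about log2 1 or less. No probe passed with any 1 array left out.

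The difference between overexpressors and SA compares both sets on arrays with the same dyes, so that a fixed dye effect cancels in part, less so for dim probes, whose ratios are compressed more in the lines than at 5 to 24 h. Here 14 probes were called, 13 with a lower ratio in the overexpressors than under SA and 1 with a higher one. A lower ratio here need not lie below the vector control. The lowest were AT5G03350 (difference at least as large as -6.11, since its treated channel was saturated at 10 and 24 h of SA; adjusted p = 0.0399), LURP1 (-5.30, 0.0399), UGT76B1 (-4.75, 0.0442) and ERD5, proline dehydrogenase (-3.27, 0.0399), and the 1 higher was AT5G50730 (1.88, 0.0424). AT5G03350 had 2.75 and 3.92 at 2 and 5 h and was at least 12.3-fold and 9.42-fold higher at 10 and 24 h, and LURP1 had 3.65, 3.12, 3.85 and 3.27. Both were below the vector control in both lines, while UGT76B1 (0.15 and 0.08 in lines 1 and 2) and ERD5 (0.10 and 0.29) stood near it. AT5G50730 had 0.22 and 0.58 in the lines and a mean of -1.49 under SA. Calls numbered 0 without the 5 h array, without the 10 h array, without line 1 or line 2 (where the spread comes from the SA arrays alone) or with the file layout as a block, 61 without the 2 h array and 28 without the 24 h array. Calls numbered 7 without saturated probes and 10 without background correction, with 0 higher in each, so AT5G50730 was not called there. Other processing gave up to 93 (median centring, 19 higher and 74 lower).

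The last comparison asks whether the overexpressors share the SA response. By the test they shared 0 genes, because limma called 0 in the overexpressors (995 at an unadjusted p under 0.05). By size, 5 genes called higher under SA were at least 2-fold higher in both lines, where independent lists would share 0.645. They were SIB1, GRP3S, GSTF2, HIR2 (1.24 and 2.01), of the hypersensitive-induced reaction family, and COBL5 (1.16 and 1.06). SIB1 is the overexpressed gene, so its place was fixed by the construct and only the other genes bear on sharing. The treated channel of GRP3S was saturated at 5, 10 and 24 h of SA. A further 4 SA-raised genes were at least 2-fold lower in both lines, where 0.308 would be shared: AT5G03350, LURP1, WRKY54 and AT1G19960. These counts of 5 and 4 became 16 and 6 with the offset of 16, 19 and 6 in the authors' ratio table, 48 and 13 with the scanner software's ratios and 52 and 3 under median centring, where limma's own calls shared 93. No gene called lower under SA was 2-fold in both lines, with 0.220 and 0.105 expected higher and lower. All these expectations treat probes alike, although bright probes reach 2-fold more readily than dim ones in both sets of arrays. Across 21262 probes, which are not independent replicates, the SA mean and the mean of the lines correlated with r = 0.247 and rho = 0.230. Line 1 alone gave r = 0.220 and line 2 r = 0.200, and the lines correlated with each other with r = 0.230 and rho = 0.278. Since all arrays share the dye orientation, a fixed dye effect of the probes would add to these correlations by an amount the design cannot separate.

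**Figure D4:**
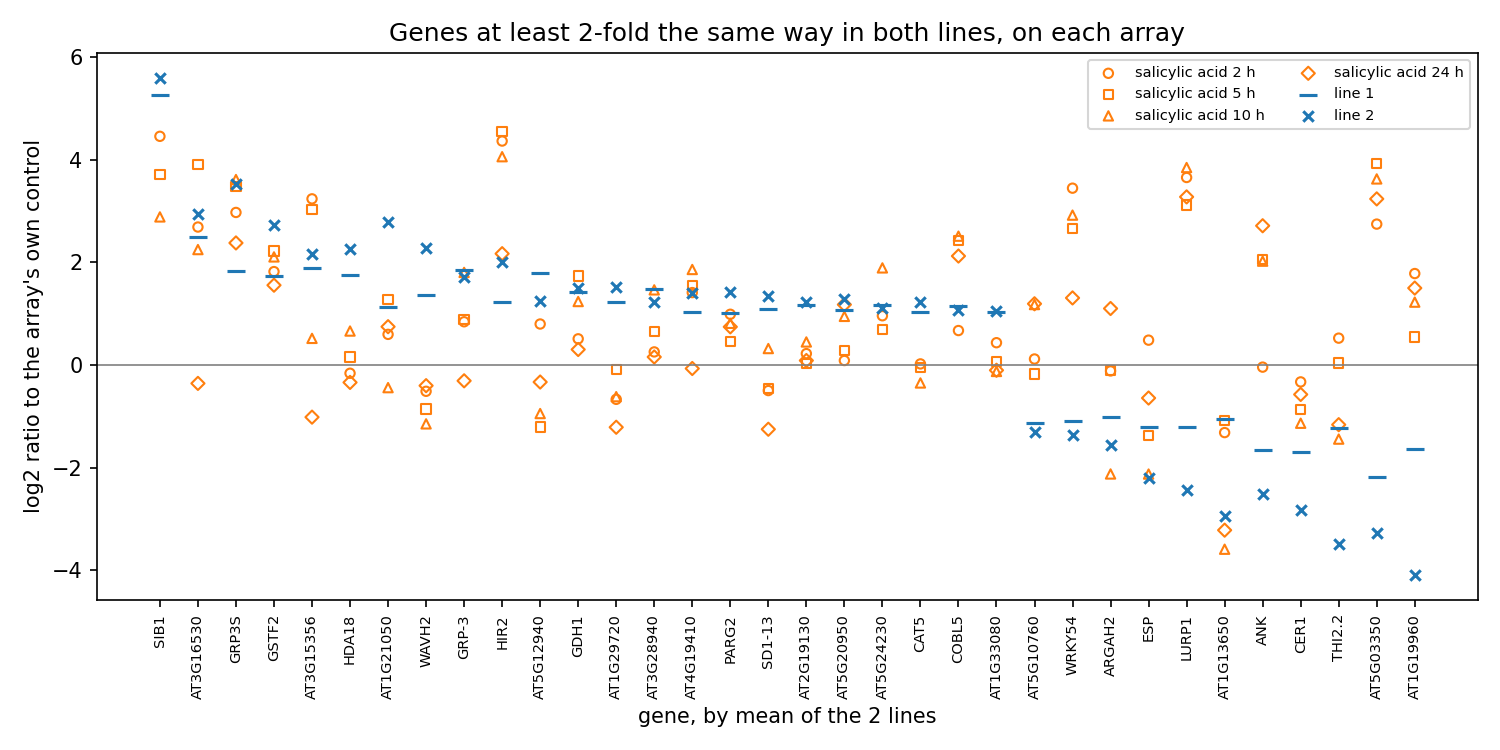
Log2 ratio to the array's own control of the 34 genes at least 2-fold the same way in both overexpressor lines, ordered by the mean of the lines, with lines in blue and the 4 SA times in orange. SIB1 is at the left with 5.25 and 5.59, and LURP1, AT5G03350 and WRKY54 at the right combine negative line values with positive SA values.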

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

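Tests of dye trend, fixed dye effect, time of day and transgene level below were chosen after the results were seen; the tests of scatter and of brightness were set before their results. The differences between times and between lines in the first paragraph were not tested.

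At some SA times a ratio was at least 2-fold one way and at others 2-fold the other way. AOS of jasmonate synthesis ranged over 2.54, from 1.17 at 2 h to -1.37 at 5 h, and the lectin gene AT3G15356 over 4.25, from 3.24 at 2 h to -1.01 at 24 h. GRP7 ranged over 4.14, from 2.53 at 10 h to -1.61 at 24 h, LHY over 3.77, from 1.2 at 5 h to -2.57 at 10 h, and the chaperone gene SHD over 5.25, from 2.61 at 10 h to -2.64 at 2 h. The abscisic acid and dehydration list had a median of 0.23 at 2 h and its lowest, -1.02, at 24 h. AT2G05540 was the only gene at least 2-fold in opposite directions in the lines, at -1.22 in line 1 and 2.00 in line 2, a difference of 3.22. The circadian clock list had a median of 0.20 in line 1 and -0.75 in line 2.

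The first pattern is the set of 4 genes called higher under SA and at least 2-fold lower in both lines. A difference in sampling time stays open: the largest clock gene ratio in line 1 was 0.752, and setting it against these genes decides nothing, since they were chosen for being at least 2-fold lower there. An intensity-dependent dye trend stays open too: under median centring 2 of the 4 genes remain in a set of 3. A fixed dye effect alone would not give the opposite signs, as the 4 genes were above 0 at all 4 SA times on the same dyes, but for the size of the line ratios it cannot be told apart from the transgene, because dyes were never swapped. Per the labels the lines received no SA, so their response to it was not measured, and no biological explanation was tested.

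The second pattern is the clock: 0 of 15 clock genes reached 2-fold in line 1 and 11 did in line 2. In line 2 the morning median exceeded the evening median by 4.001, percentile 100 of 10000 random pairs, which may reflect line 2 and its control being sampled at different times of day. Line 1 is not free of it: its difference was -0.445, smaller and the other way, but at percentile 0. Wider scatter of the whole array does not account for it, since the SD of the clock list was 2.39 at percentile 100 where random lists had a median of 0.439. The SIB1 log2 ratio differed by 0.343 between the lines, with 1 array each. The clock counts were known when this was looked at, so it does not decide whether the level of SIB1 plays a part. Other differences between the lines were not tested and stay open.

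The third pattern is that genes called lower under SA leaned lower in both lines, with medians of -0.11 and -0.38 and 76.6% of their ratios below 0. Over all probes in both fits 47.8 and 49.8% were below 0 in lines 1 and 2. Genes called higher under SA had medians of 0.04 and 0.09, with 35.6 and 37.4% below 0. For the genes called lower, brightness is argued against, as both of their medians lay at percentile 0 of random lists matched on brightness. A fixed dye effect cannot be told apart from a shared response here, since it would push the same probes down on all 6 arrays. A weak overlap of SIB1 overexpression with the SA response is therefore only a possible explanation.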

How the results depend on the processing

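Gene lists without saturated probes or single SA arrays, the counts of genes 2-fold in both lines, alone or among SA-raised genes, the filter on surrogate values and normexp on background-subtracted signals were chosen after seeing the data; the cause of changes below was not tested unless stated.

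With an offset of 16 the SA calls numbered 1264, difference calls 81, genes 2-fold in both lines 68, probes at 2 h 2315 and SA-raised genes higher in both lines 16, with SIB1 at 5.77 and the correlation at 0.232. With the scanner software's ratios these were 1386, 71, 348, 4502 and 48, with 13 SA-raised genes lower in both lines, SIB1 at 6.05, the correlation at 0.198 and 1 list passing in the overexpressors. With the authors' ratio table they were 1425, 35, 70, 2192 and 19, with SIB1 at 5.73 and 5 lists in the overexpressors. Median centring gave 412 overexpressor calls, 93 difference calls, 138 genes in both lines, 93 shared calls, 52 SA-raised genes higher in both lines, SIB1 at 6.08 and now past the threshold, 4 lists, and a photosynthesis median of 0.36 in the overexpressors, the single reversal. In the SA fit 12 lists passed under median centring, 10 upward and 2 downward, against 13 in the main fit, 10 upward and 3 downward. Without background correction 1 list passed in the overexpressors.

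With an estimated correlation 0 lists passed in the SA or the overexpressor fit. With fry 12 lists passed in the SA fit, 9 higher and 3 lower, and 0 in the overexpressor fit. The 12 include root markers (fry adjusted p = 0.047), which did not pass camera. Chaperones and photosynthesis genes passed camera but not fry (fry adjusted p = 0.219 and 0.066, saturated members included). Difference calls numbered 30 with both channels above background, 24 with background-subtracted signals, 42 with an intensity trend (which gave 1 overexpressor call), 7 without saturated probes and 0 with file layout as a block. Without a fold floor the SA calls numbered 1670. At 3-fold, 495, 837, 974 and 686 probes passed at 2, 5, 10 and 24 h, fewer by construction. Genes 2-fold in both lines and at these times the same way numbered 8, 12, 16 and 7, and the opposite way 4, 5, 7 and 10. Leaving out 1 array gave 0 to 819 SA calls, 0 to 61 difference calls, 0 trend calls and 12 to 13 SA lists; with 1 line left, the overexpressor fit takes its spread from the SA arrays (0 calls) and says nothing about stability.

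Of the other values of whole comparisons 135 stayed within 1.5 times the count or within the SD of the lines. For named genes and lists 924 stayed on the same side of the threshold, or if not called within their SD, 106 lost the threshold, 13 gained it and 28 moved. Slide and scan day were not given, and the layout crosses groups only for the difference, so no other block was run. No paired analysis was possible because the SA groups have 1 array each and the lines are not paired with them. Signal over background limits the 2 h array and both lines, where ratios of dim probes are compressed.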

Other observations

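The genes, lists and counts in this part were picked after the data were seen. Several heat shock and senescence genes called higher under SA were also high in line 2 and near or below 0 in line 1: SAG21 had 2.62 and -0.01, ASN1, a dark-induced asparagine synthetase, 2.56 and -0.46, and HSP70-4 2.23 and -0.22. Of the 16 heat shock genes, 7 were at least 2-fold higher in line 2, whose list median of 0.43 lay at percentile 99.99 of random lists, and 0 in line 1. On the same array 5 of the 17 abscisic acid and dehydration genes were at least 2-fold lower and 0 in line 1, among them COR15B at -3.35 and RD29A at -2.67 in line 2 and 0.36 and -0.14 in line 1. None of these differences between lines was tested. On the line 2 array 11 of 15 clock genes were also at least 2-fold, so a difference in sampling time stays open for these genes. Its log2 ratios were more widely spread as well, with an SD over all probes of 0.443 against 0.167 in line 1.

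Among the SA times, 588 probes were at least 2-fold lower at 24 h alone, more than at 2, 5 or 10 h alone (129, 229 and 415), while 498 were higher at 10 h alone. The 24 h array also lost 8.01% of its spots to outlier marks.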
